A study of Arabidopsis thaliana with 9 samples.

How the data were processed

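RNA from detached leaves of 9 samples was measured on 1 Affymetrix array each, in 3 groups of 3: control, BrvC 6 h and BrvC 48 h. Plants had grown for 4 weeks in soil under 16 h of light at 21 °C and 8 h of dark at 19 °C, per the labels' protocols, and a sample pooled 10 to 15 leaves. Amplified cDNA was labelled with biotin, per the labels' protocols. The authors deposited 1 table of log2 values per probe set, with 1 column per array, and the submitters' processing notes name oligo, RMA and limma without versions. RMA corrects background, normalizes arrays by quantiles and summarizes probes on the log2 scale, so that differences of low signals are compressed. The log2 scale was read from the values themselves, which ran from 0.298 to 13.9. Over all 38408 entries the array medians still differed, from at most 3.93 in control to at least 4.17 at 6 h. The genome build and the array annotation used by the authors were not given in the sources used here, and no coordinates are printed.

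Names came from a table that pairs probe sets with genes. Of 38408 entries in the value table, 16722 had 1 gene, 759 had several genes and were not named or tested, and 20927 were not listed and are unnamed here. For 146 genes with several entries, the entry with the highest mean over all arrays was used and 172 others were left out, which left 16550 genes with no filter on level. Symbols were updated through the RefSeq gene table of assembly TAIR10.1, where 16411 genes were found and 139 were not. A symbol was carried by 1793 genes, and 14757 had a locus name alone. Close copies within gene families can share probes, so that values of such genes are uncertain. A planned rule took chloroplast genes by locus names that the table did not use, and the genes placed on the plastid genome by the reference table were taken instead.

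A linear model with 1 mean per group was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 6 residual and 7.04 prior degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over 16550 genes per comparison, from a two-sided moderated test, and a gene counted as changed at 0.05. Fold changes are differences of group means on the log2 scale. Before the data were examined, 37 gene lists with 528 named members were fixed from general knowledge, covering photosynthesis, metabolism, hormones, stress, defence and markers of other cell types, with the chloroplast-encoded and mitochondria-encoded genes as 2 of the 37. Of the named members 92 had a probe set listed for that 1 gene and are called measured here. The others may lie among the entries not listed or with several genes, so that the 92 need not stand for their lists. Measured were 4 of 15 hypoxia, 4 of 16 photosystem and 3 of 16 Calvin cycle members. By this count 9 lists had no measured member, 16 had 1 to 3 and were described, and 12 with 4 or more were tested. Lists were tested with camera in limma at a preset correlation of 0.01, adjusted over the 12 lists, with camera at an estimated correlation and fry beside it. Camera compares a list with the other genes, and fry tests whether its genes move, on balance, one way.

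The genes named in the text followed a rule fixed before the data were examined. For each comparison with control the 7 largest rises and 7 largest falls were taken among genes past the test that carried a symbol in the reference table and whose groups did not overlap, and for 48 h against 6 h the 4 and 4 largest. Each list with a camera call or at least 3 members past the test in a comparison with control gave its 2 members past the test with the largest change there. List members with a locus name alone in that table take their symbol from the list and were left out of the largest rises and falls, which mattered for HUP9 at 48 h. A gene named once may be given in the other comparisons. Other members of the fixed lists, and families named by symbol stem, were named after their values were seen.

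The replicate numbers are shared by the groups, and a pairing was checked by correlating the deviations from the group means between arrays of the same number. The correlations were 0.302, 0.242 and 0.539 for control and 48 h, all over 0.1, so that the numbers pair these groups by the rule fixed for it, as a property of the data, since the labels do not say what a number shares. They were 0.034, -0.032 and 0.012 for control and 6 h, and 0.102, -0.051 and -0.012 for 6 h and 48 h, which does not pair them. A fit with the replicate number as a block was one of the alternatives. The others were all entries of the value table, a filter on low genes, centring or renewed quantile normalization, an intensity trend with robust spread, array weights, fits to the 2 groups compared, stricter thresholds, other set tests, and leaving out each array in turn. The simulated overlaps of calls and the simulation with paired arrays, 100 runs each, were added after the results were seen. The fit and the camera test were tried on simulated data for the 6 h comparison with 16550 genes, of which 50 per size were changed. Of these, 6% were recovered at a log2 change of 0.5, 60% at 1, 92% at 2 and 100% at 3, with 9 false calls, and the list that had been shifted was found. The simulated values were independent between genes and between arrays, and a far smaller share of genes was changed than was called in the data. These rates therefore need not hold for the data.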

Results

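The data were 9 Affymetrix array profiles of total RNA from detached leaves of Arabidopsis thaliana ecotype Col-0, aged 30 days. Brevicompanines are fungal alkaloids, and BrvC is the member of this group named in the labels. Leaves floated in medium with 50 µM BrvC in darkness were sampled at 6 h (3 arrays) or 48 h (3 arrays), and 3 control arrays came from leaves given the solvent, 0.05% DMSO. The labels call the replicates biological and give 1 control group without its time in the dark. The array value was a log2 signal per probe set, and 16550 genes were tested. The number of arrays, 3 per group, limits the precision. The mean correlation between arrays of a group was 0.981 in control, 0.991 at 6 h and 0.987 at 48 h, and no pair of columns was identical. Between groups it was 0.943 for control and 6 h, 0.969 for control and 48 h, and 0.958 for 6 h and 48 h. The first principal component held 51.9% of the variance and set the 6 h arrays (scores -56.1 to -54.7) apart from the 48 h arrays (13.6 to 18.5) and the controls (33.5 to 43.8).

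**Figure D1:**
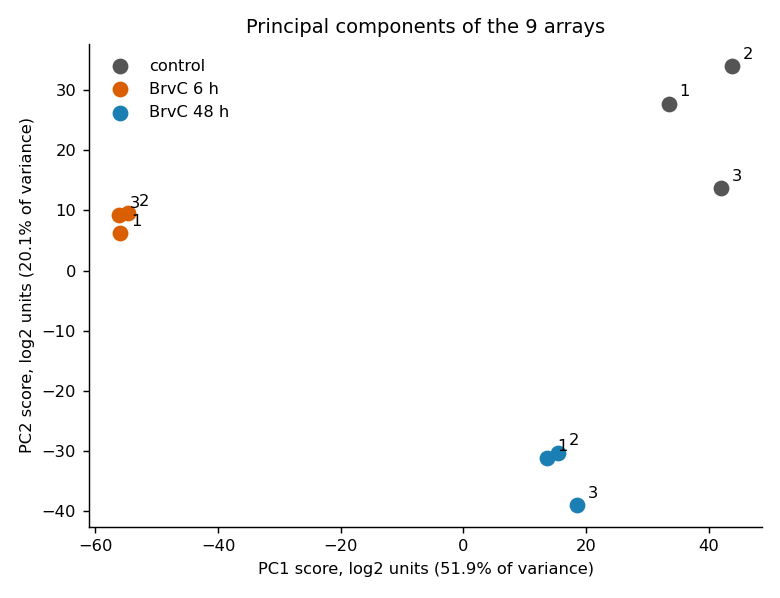
Scores of the 9 arrays on the first 2 principal components of the 16550 tested genes, in log2 units, with 1 point per array, coloured by group and numbered by replicate. The first component (51.9% of the variance) separated 6 h from the other groups, and the second (20.1%) separated control from 48 h.

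The first comparison asked which genes differed from control after 6 h with BrvC. All 4 measured hypoxia genes, 4 of 5 early immune genes and 4 of 5 chlorophyll synthesis genes rose, and 7 of 11 autophagy genes fell. Camera called these lists at its preset correlation, and none of them with an estimated correlation (adjusted p = 0.113, 0.149, 0.198 and 0.198). PRN, a cupin-fold protein, had the largest rise of a gene with a symbol, from a log2 value of 3.04 ± 0.21 (SD, n = 3) to 7.73 ± 0.24. OSM34, an osmotin-like protein, had the largest fall of a gene with a symbol, from 11.82 ± 0.27 to 6.89 ± 0.14 (SD, n = 3). In all, 4531 of 16550 genes changed (27.4%) by limma with Benjamini-Hochberg adjustment at 0.05, of which 2351 were higher and 2180 lower. At least 2-fold changes were found for 1245 higher and 1007 lower genes. Over all value table entries, named or not, 64.0% of the calls were higher, against 51.9% over the named genes and 48.6% of these after centring each array. The 3 arrays of one group lay wholly above the 3 of the other for 40.3% of genes, where chance gives 10%.

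Among the genes with a symbol that rose most were the high-affinity nitrate transporter NRT2.5 (log2 fold change 4.01, SE 0.20, limma adjusted p = 2.38e-08) and the cold-inducible KIN2 (3.96, SE 0.27, adjusted p = 3.03e-07). The auxin-conjugating enzyme GH3.3 (3.78, SE 0.28), the transcription factor TCP1 (3.73, SE 0.32), the auxin-response repressor IAA29 (3.46, SE 0.18) and the glutathione transferase GSTU20 (3.43, SE 0.24) followed. The largest falls of genes with a symbol after OSM34 were those of the beta-glucosidase BGLU46 (-4.23, SE 0.23), the sugar transporter SWEET2 (-3.91, SE 0.33) and GH3.17 (-3.86, SE 0.21), a relative of GH3.3. They were followed by MCCB of leucine breakdown (-3.69, SE 0.21), the asparaginase ASPGB1 (-3.41, SE 0.32) and the sulfurtransferase STR18 (-3.24, SE 0.22). Adjusted p was 4.34e-06 or lower for each of these genes with a largest rise or fall, the value of ASPGB1. That their groups did not overlap was a condition of the choice.

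All 4 measured genes of the hypoxia list rose, with a median log2 fold change of 2.23 (4 adjusted over the list alone; camera in limma, adjusted p = 1.26e-05, and adjusted p = 0.113 with an estimated correlation). They were HRA1 (2.80, SE 0.24), HUP9 (2.34, SE 0.24), the lactate dehydrogenase LDH1 (2.12) and HUP6 (1.99). Of 5 early immune genes 4 rose (5 adjusted over the list alone), with a median of 1.07 (camera adjusted p = 0.000416, and adjusted p = 0.149 with an estimated correlation). The ubiquitin ligase PUB22 rose by 2.26 (SE 0.22) and the transcription factors WRKY29 and WRKY22 by 1.88 (SE 0.17) and 1.07. Chlorophyll synthesis genes rose in 4 of 5 cases (4 adjusted over the list alone), with a median of 0.73 (camera adjusted p = 0.00561, and adjusted p = 0.198 with an estimated correlation). PORB, which reduces protochlorophyllide, rose by 1.38 (SE 0.18) and GSA1 by 0.84 (SE 0.19), while CHLM had 0.16 (adjusted p = 0.614). Autophagy genes fell in 7 of 11 cases (8 adjusted over the list alone), with a median of -1.10 (camera adjusted p = 0.000547, and adjusted p = 0.198 with an estimated correlation). Both ATG8H (-2.16, SE 0.24) and APG8A (-2.12, SE 0.27) encode ubiquitin-like proteins of the autophagosome membrane. Chloroplast-encoded genes rose in 17 of 63 cases (17 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 1.26e-05, and adjusted p = 0.445 with an estimated correlation). The plastid RNA polymerase genes rpoC2 (1.76, SE 0.16) and rpoB (1.30, SE 0.21) led this list.

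Some lists held genes that moved in opposite directions and did not pass the camera test. Of 4 abscisic acid genes, KIN2 and COR15A (2.56, SE 0.39) rose, COR47 fell (-0.75), and KIN1, a close copy of KIN2, had 0.03 (list adjusted p = 0.139; 2 higher and 1 lower adjusted over the list alone). Of 7 auxin response genes, GH3.3 and IAA29 rose while WES1 (-2.84) and GH3.1 (-0.67) fell (list adjusted p = 0.466; 2 and 2 adjusted over the list alone). Of 4 heat shock genes, HSP15.7 (-2.66, SE 0.18) and ROF2 (-0.78) fell and HSP17.6C rose (1.11, SE 0.32) (list adjusted p = 0.443; 2 lower and 1 higher adjusted over the list alone). The calls of HSP17.6C (0.69 without 6 h replicate 3), ROF2, RCA, JRG21 (without 6 h replicate 3; 0.67 and still called without control replicate 1) and ndhF at 6 h were each lost in limma when certain single arrays were left out, that of RCA also after renewed quantile normalization (-0.36). The comparison cannot separate BrvC from the time in the dark unless the controls had the same 6 h, which the labels do not say.

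**Figure D2:**
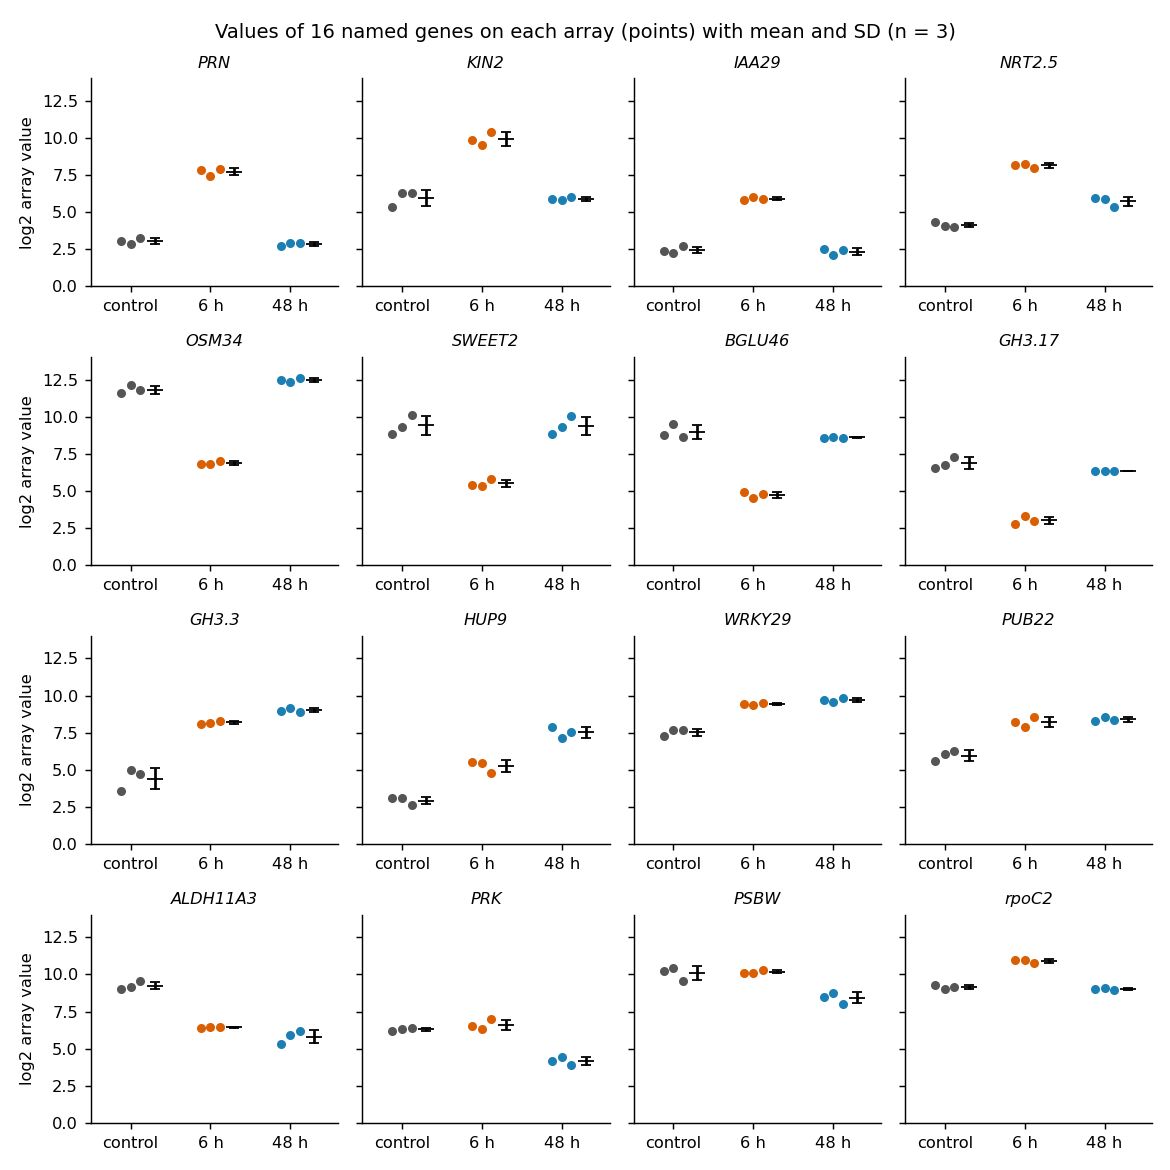
Log2 array values of 16 named genes in control, BrvC 6 h and BrvC 48 h leaves, with 1 point per array and the mean with SD (n = 3) to the right. PRN, KIN2 and IAA29 were high at 6 h alone among the 3 groups, OSM34, SWEET2, BGLU46 and GH3.17 were low at 6 h, and GH3.3, HUP9, WRKY29 and PUB22 were above control at both times.

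After 48 h with BrvC, 4 of 4 photosystem genes and 3 of 3 Calvin cycle genes fell, and 3 of 4 hypoxia genes and 3 of 5 early immune genes rose. BrvC cannot be separated here from the time in the dark unless the controls had the same 48 h, which the labels do not say. The camera call of the early immune list was lost with an estimated correlation (adjusted p = 0.0685), and those of the photosystem and hypoxia lists were not. All 4 measured photosystem subunit genes fell, with a median log2 fold change of -1.57 (4 adjusted over the list alone; camera adjusted p = 4.95e-06, and adjusted p = 0.0305 with an estimated correlation). The photosystem II subunits PSBY (-2.09, SE 0.23) and PSBW (-1.66, SE 0.24) fell with PSAN (-1.48) and PSAE-1 (-1.38) of photosystem I. All 3 measured Calvin cycle genes also fell (3 adjusted over the list alone), a list too small for a set test. They were the phosphoribulokinase PRK, from 6.29 ± 0.08 to 4.18 ± 0.28 (SD, n = 3), the Rubisco activase RCA (-1.42, SE 0.18) and SBPASE (-0.83). In all, 1762 of 16550 genes changed (10.6%) by limma with Benjamini-Hochberg adjustment at 0.05, of which 898 were higher and 864 lower. The share of higher calls was 51.0%, against 59.5% over all value table entries and 49.6% after renewed quantile normalization. At least 2-fold changes were found for 375 higher and 433 lower genes. The groups did not overlap for 25.1% of genes, where chance gives 10%.

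GH3.3 had the largest rise of a gene with a symbol in the reference table, from 4.41 ± 0.72 to 9.03 ± 0.13 (SD, n = 3; limma adjusted p = 6.72e-07). HUP9, which has a locus name alone there and takes its name from the hypoxia list, rose by as much (4.62, SE 0.24). Of the genes with a symbol in the reference table, PUB22 (2.44, SE 0.22), WRKY29 (2.15, SE 0.17), the isocitrate lyase ICL of the glyoxylate cycle (2.14, SE 0.26), ATL4H (2.14, SE 0.24), the dioxygenase JRG21 (1.98, SE 0.29) and GSTU20 (1.97, SE 0.24) followed. The largest falls of genes with a symbol were those of ALDH11A3, a glyceraldehyde-3-phosphate dehydrogenase (-3.44, SE 0.22, adjusted p = 1.11e-06), and the methyltransferase FAMT (-2.70, SE 0.23). They were followed by the transcription factor BZIP61 (-2.56, SE 0.31), the beta-glucosidases BGLU27 (-2.47, SE 0.20) and BGLU31 (-2.38, SE 0.33), the photorespiratory hydroxypyruvate reductase HPR (-2.40, SE 0.18) and PAP85 (-2.38, SE 0.26).

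Hypoxia genes rose in 3 of 4 cases (3 adjusted over the list alone), with a median of 1.86 (camera adjusted p = 4.16e-06, and adjusted p = 0.0416 with an estimated correlation). HUP9 rose from 2.92 ± 0.25 to 7.54 ± 0.37 (SD, n = 3), and HRA1 by 1.88 (SE 0.24), while LDH1 had 0.20 (adjusted p = 0.591). Early immune genes rose in 3 of 5 cases (4 adjusted over the list alone), with a median of 1.12 (camera adjusted p = 7.99e-05, and adjusted p = 0.0685 with an estimated correlation). Heat shock genes fell in 2 of 4 cases (2 adjusted over the list alone), namely HSP15.7 (-1.95, SE 0.18) and ROF2 (-1.95, SE 0.21), with a median of -0.96 (camera adjusted p = 0.0239, and adjusted p = 0.158 with an estimated correlation). With the replicate number as a block in the arrays of control and 48 h alone, which the numbers pair, the heat shock list was not called (adjusted p = 0.0719, in a range of 0.00608 to 0.158 over the alternatives with camera). Of 9 xenobiotic detoxification genes 2 rose and 1 fell (4 and 1 adjusted over the list alone), with a median of 0.50 (camera adjusted p = 0.0427, and adjusted p = 0.158 with an estimated correlation). The efflux carrier DTX3 rose by 1.26 (SE 0.21) and the glucosyltransferase UGT73B5 by 0.97 (SE 0.29, adjusted p = 0.0499), while the glutathione transferase GSTF3 fell (-0.79). Chloroplast-encoded genes fell in 2 of 63 cases (1 adjusted over the list alone), ndhF (-1.25, SE 0.24) and ndhH (-0.61, SE 0.17). The median of this list was -0.18 (camera adjusted p = 0.00236, and adjusted p = 0.755 with an estimated correlation). Its camera call was lost without 48 h replicate 2 (adjusted p = 0.0999), that of heat shock proteins without control replicate 3 (adjusted p = 0.108), and that of xenobiotic detoxification without any 1 of 48 h replicate 2 (0.0701), control replicate 1 (0.115) or control replicate 3 (0.0667). The xenobiotic call also ended without low genes (0.103), after renewed quantile normalization (0.053) and with an intensity trend (0.0503), and without low genes the heat shock list had 1 member and was not tested. UGT73B5 and ndhH lost their calls when single arrays were left out, as did the smaller differences of OSM34 (0.65), MCCB (-0.76) and ASPGB1 (-1.09) from control at 48 h. With all arrays of control and 48 h kept, each of these calls was also lost in the fit to these groups alone. Those of UGT73B5 and MCCB were lost after renewed quantile normalization too, and those of ndhH and ASPGB1 with array weights.

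**Figure D3:**
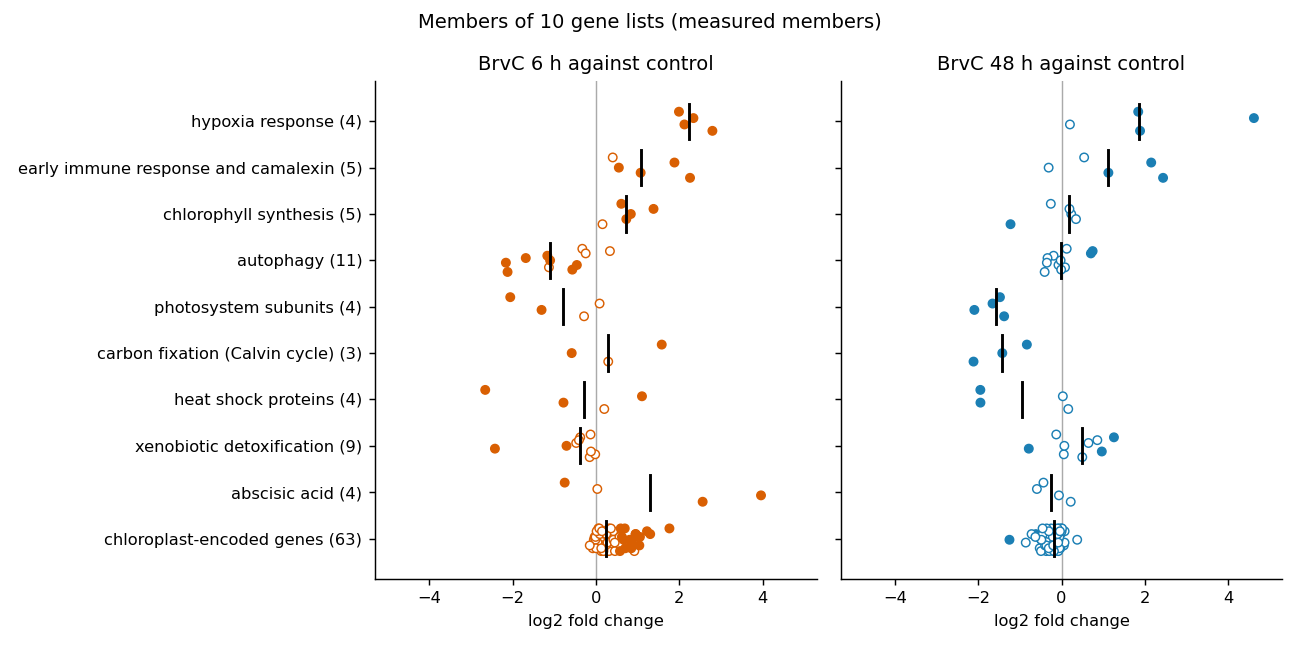
Log2 fold changes against control of the measured members of 10 gene lists at 6 h and 48 h, with 1 point per gene, filled where limma's adjusted p was under 0.05, and a bar at the list's median. The hypoxia list had a median of 2.23 at 6 h and 1.86 at 48 h, and the photosystem list -0.79 and -1.57.

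The third comparison set the 48 h leaves against the 6 h leaves, both with BrvC. OSM34, SWEET2, BGLU46 and CHAT, an acetyltransferase of leaf volatiles, were higher at 48 h, and PRN, KIN2, BZIP61 and IAA29 were lower. OSM34 differed by 5.58 (SE 0.18, limma adjusted p = 2.19e-09) and PRN by -4.89 (SE 0.18, adjusted p = 4.53e-09). SWEET2 differed by 3.87 (SE 0.33), BGLU46 by 3.86 (SE 0.23), CHAT by 3.31 (SE 0.19), KIN2 by -4.02 (SE 0.27), BZIP61 by -3.89 (SE 0.31) and IAA29 by -3.56 (SE 0.18). In all, 3356 of 16550 genes changed (20.3%) by limma with Benjamini-Hochberg adjustment at 0.05, of which 1592 were higher at 48 h and 1764 lower. The share of higher calls was 47.4%, against 41.4% over all value table entries and 51.5% after centring each array. At least 2-fold changes were found for 735 higher and 830 lower genes.

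Autophagy genes were higher at 48 h than at 6 h in 7 of 11 cases (10 adjusted over the list alone), with a median of 0.97 (camera adjusted p = 2.21e-06, and adjusted p = 0.125 with an estimated correlation). ATG8H differed by 1.81 (SE 0.24) and APG8A by 1.71 (SE 0.27). Xenobiotic detoxification genes were higher in 6 of 9 cases (7 adjusted over the list alone), with a median of 1.08 (camera adjusted p = 0.000272, and adjusted p = 0.0729 with an estimated correlation). Chlorophyll synthesis genes were lower in 4 of 5 cases (5 adjusted over the list alone), with a median of -0.87 (camera adjusted p = 0.00072, and adjusted p = 0.125 with an estimated correlation). Abscisic acid genes were lower in 2 of 4 cases, KIN2 and COR15A (2 adjusted over the list alone), with a list median of -1.48 (camera adjusted p = 0.0291, and adjusted p = 0.278 with an estimated correlation). That call was lost without 6 h replicate 3 (adjusted p = 0.0536), and without low genes the list had 3 members and was not tested. Chloroplast-encoded genes were lower in 31 of 63 cases (33 adjusted over the list alone), with a median of -0.59 (camera adjusted p = 1.24e-11, and adjusted p = 0.278 with an estimated correlation). The plastid genes ndhF (-2.06, SE 0.24), rpoC2 (-1.86, SE 0.16) and rpoB (-1.75, SE 0.21) were among them. PRK (-2.41, SE 0.21), PSBW (-1.74, SE 0.24) and ICL (2.09, SE 0.26) also differed between the times, whereas PUB22 had 0.18 (adjusted p = 0.68) and WRKY29 0.27 (adjusted p = 0.353). The treated groups differed in both age of treatment and time in the dark, and calls of GH3.3, GSA1, HRA1, HSP15.7, HSP17.6C (-0.66 without 6 h replicate 3), JRG21, PSBY and UGT73B5 in this comparison were lost when single arrays were left out. That of GH3.3 was also lost after renewed quantile normalization (0.66).

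**Figure D4:**
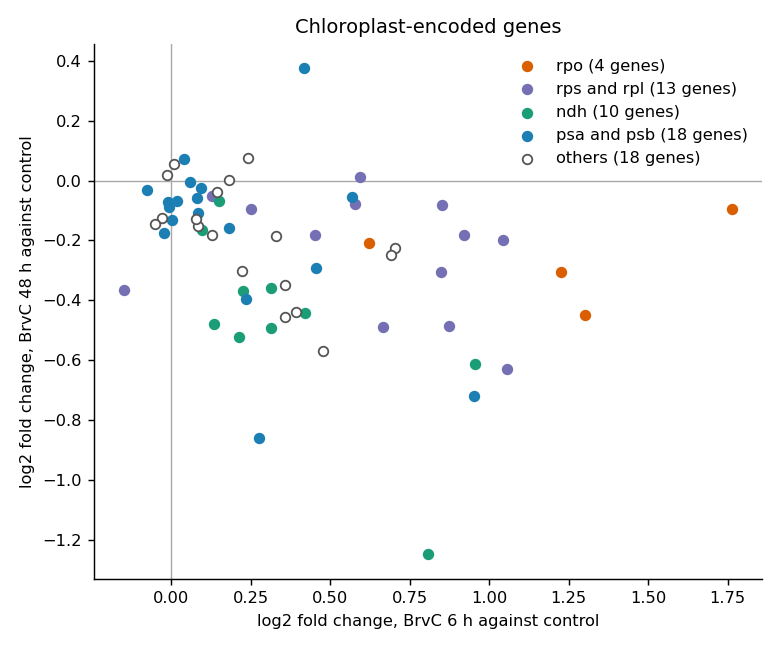
Log2 fold changes of 63 chloroplast-encoded genes, BrvC 6 h against control (horizontal axis) and BrvC 48 h against control (vertical axis), with 1 point per gene, coloured by the prefix of the symbol. The RNA polymerase genes (rpo) lay farthest to the right, with a median of 1.26 at 6 h, and ndhF lay lowest, at -1.25 at 48 h.

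The fold changes at 6 h and 48 h were set against each other to see how far the genes that moved at 6 h were those that moved at 48 h. GH3.3, GSTU20, PUB22, WRKY29, HRA1 and HUP9 were higher than control at both times, and ALDH11A3, FAMT, BGLU27, BGLU31, PAP85, HPR and HSP15.7 were lower at both. BZIP61 was higher at 6 h (1.33, SE 0.31, and 0.89 without control replicate 2) and lower at 48 h, as SBPASE was (1.58 at 6 h). In limma's calls, 577 genes were higher at both times and 539 lower at both, where independent lists, which leave out the shared controls, would share 127.6 and 113.8. Simulated unchanged groups with controls in common, which leave out the effects, shared 0 and 0 in limma, where groups without effects give almost no calls. At an unadjusted p under 0.05 they shared on average 103.5 and 105.1, against 1177 and 1186 observed. With control and 48 h arrays of the same number paired in the simulation, the averages were 45.0 and 47.0. The 3 controls were too few to split, and part of the overlap beyond independent lists may come from the shared controls. A further 66 genes were higher at 6 h and lower at 48 h, and 60 were lower and then higher. Of the 4531 genes called at 6 h, 2389 (52.7%) were called in the opposite direction at 48 h against 6 h, where independent lists would share 460.3. Simulated unchanged groups shared 0 in limma, which says nothing on this overlap, since groups without effects give almost no calls. At an unadjusted p under 0.05 the simulated groups shared on average 206.7, against 3542 observed. With control and 48 h arrays of the same number paired in the simulation, the average was 329.8. Part of this overlap may come from the 6 h arrays that both comparisons use. Across the 16550 genes, which are not independent replicates, the correlation of the 2 fold changes was 0.53 (Pearson) and 0.52 (Spearman), and 70.6% of genes had the same sign. Simulated unchanged groups that shared 3 simulated controls gave a correlation of 0.50 and the same sign in 66.6% of genes. The covariance was 0.197 against a simulated 0.0275, a difference of 0.17. That simulation took the arrays as independent, and a second one, in which control and 48 h arrays of the same number deviated together (correlation 0.361), gave a correlation of 0.40 and a covariance of 0.0176.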

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

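All tests of explanations in this part were chosen after the results were seen, except the matched comparison of chloroplast genes and the counts over other splits. Effects at 48 h and 6 h were compared directly by limma's contrast of 48 h with 6 h, in which the shared controls cancel. Of 47 named genes 40 differed, against 20.3% of all 16550 genes. The named genes had been chosen in part for large changes in these comparisons, which raises their share. Camera called 5 lists at the preset correlation and 0 with an estimated correlation. Values are the effect at 48 h minus that at 6 h, in log2 units. Genes higher at 6 h than at 48 h were PRN (-4.89), KIN2 (-4.02), BZIP61 (-3.89), IAA29 (-3.56), NRT2.5 (-2.42), COR15A (-2.34), TCP1 (-2.09), GSTU20 (-1.46), PORB (-1.19), HSP17.6C (-1.07), HRA1 (-0.91) and GSA1 (-0.60). The plastid genes ndhF (-2.06), rpoC2 (-1.86), rpoB (-1.75) and ndhH (-1.57) were higher at 6 h too, and so were PRK (-2.41), PSBW (-1.74), HPR (-1.39), ROF2 (-1.17), RCA (-0.84) and PSBY (-0.79). Genes lower at 6 h than at 48 h were OSM34 (5.58), SWEET2 (3.87), BGLU46 (3.86), CHAT (3.31), GH3.17 (3.31), MCCB (2.93), ASPGB1 (2.32), STR18 (1.85), ATG8H (1.81) and APG8A (1.71). HUP9 (2.28), ICL (2.09), DTX3 (1.63), ATL4H (1.58), UGT73B5 (1.08), JRG21 (0.93), GH3.3 (0.84) and HSP15.7 (0.71) were higher at 48 h as well. The lists called at the preset correlation were abscisic acid (median -1.48), chlorophyll synthesis (-0.87), chloroplast-encoded genes (-0.59), autophagy (0.97) and xenobiotic detoxification (1.08). All 5 calls were lost with an estimated correlation (adjusted p = 0.278, 0.125, 0.278, 0.125 and 0.0729).

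Entries without a listed gene also carried a signal. The 7083 entries before the first listed one were higher than control by a median of 0.55 at 6 h and 0.41 at 48 h.

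The control arrays lay nearer to the 48 h arrays than to the 6 h arrays. The distance from control to 6 h was 1.34 times that from control to 48 h as deposited. After renewed quantile normalization it was 1.36 times (1.33 to 1.38 with single arrays left out). Differences left in the arrays' distributions of the tested genes thus do not make this ratio. The deposited values were already normalized by quantiles, so the repeat could change little and does not decide on other effects of array scaling. On the path from 6 h (0) to 48 h (1), control lay at 0.839 over the 1592 genes that were higher at 48 h and at 0.921 over the 1764 that were lower. Control and 48 h arrays of the same number deviated together (correlations of 0.242 to 0.539), and control and 6 h arrays did not (-0.032 to 0.034), so that the 6 h leaves could also have been handled apart from the others. Control leaves kept in the dark for longer than 6 h, a BrvC effect at 6 h that was gone by 48 h and a 6 h group handled apart cannot be told apart, because neither the controls' time in the dark nor the handling is given.

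The rise of the 7083 unlisted entries was set against listed genes of the same level. A shift of background or scaling common to all dim entries would move dim listed genes alike. Their median difference, however, was -0.113 at 6 h and -0.0852 at 48 h. A technical shift that touches only the unlisted entries is not decided by this, since they may differ in kind from listed genes. Of the entries 78.2% were higher at 6 h and 74.3% at 48 h, but medians above 0 already fix a share over 50%, so that this does not tell how many carry the shift. The other 13844 unlisted entries had medians of 0.00184 and -0.000593. What the entries measure stays open, and no biological explanation was tested, as they have no name here.

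Of 63 chloroplast-encoded genes 17 were higher at 6 h than in control and 31 higher at 6 h than at 48 h. The chloroplast genes had a median of 0.25 at 6 h against control. For 10000 nuclear lists of the nearest levels it was -0.0557 (95% of them between -0.104 and 0.0796). Scaling that moves nuclear genes of those levels alike is thus a poor account of the list's median. The mean of the chloroplast genes over matched nuclear genes was 0.74 ± 0.08 at 6 h, 0.24 ± 0.13 in control and -0.05 ± 0.15 at 48 h (SD, n = 3). These means do not balance around 0, so that the matched genes were dimmer on average. The matched lists therefore do not decide on scaling of the brightest probe sets. The 3 arrays at 6 h against the other 6 gave an exact permutation p of 0.0119, two-sided, the smallest that 84 splits can give. This permutation was chosen in place of a first test after the 6 h arrays had been seen to be the highest, so that it does not speak against chance variation between arrays. Camera with an estimated correlation did not set the list apart from other genes (adjusted p = 0.445 at 6 h). Control lay at 0.633 on the path from 6 h to 48 h. Chance variation, another dark time of the controls, a 6 h group handled apart and an effect of BrvC cannot be told apart. Nor can scaling of the brightest probe sets be told apart from these.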

How the results depend on the processing

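The alternatives were set before the data were examined, except the fit without the arrays numbered 3, the replicate block in the arrays of 2 groups and the count without the leading unlisted entries, which were chosen after seeing the data. Counts below are for 6 h against control, 48 h against control and 48 h against 6 h. Over all entries of the value table, which tests more features, 10484, 3824 and 6075 were called, and the correlation of the fold changes was 0.624. Without the entries before the first listed one, 9535, 4001 and 6742 were called. A stricter adjusted p of 0.01 left 3081, 921 and 2083 genes, and an adjusted p of 0.05 with at least a 2-fold change left 2252, 808 and 1565. With an estimated correlation 0, 2 and 0 lists were called (hypoxia and photosystem subunits at 48 h), and fry called 11 lists at 6 h. For photosystem subunits the estimate was 0.0056, below the preset 0.01, yet camera's unadjusted p at 48 h against control rose from 8.25e-07 to 0.00254. For xenobiotic detoxification the estimate was -0.0735, and that p rose from 0.0213 to 0.0539. A higher correlation thus does not account for the rise of p in these lists. The other called lists had estimates of 0.12 to 0.417. For them and for fry the cause was not tested. The replicate block gave 5027, 2134 and 3794 genes and 5, 6 and 5 lists, within 1.5 times of the counts reported, and ended no call of a named gene or list; in the arrays of control and 48 h alone it gave 2312 genes and the heat shock list was not called (adjusted p = 0.0719). Leaving out single arrays gave 3575 to 4649, 1256 to 2138 and 2470 to 3768 genes, 5 to 5, 4 to 7 and 4 to 6 lists and correlations of 0.504 to 0.571, and without the arrays numbered 3 in control and 48 h 1608 genes were called at 48 h. Of 2720 alternative values of named genes, 2601 kept their side of the threshold, 110 lost the call and 9 gained it. Where the main fit or the alternative gave a call, 0 turned direction. Signs were not compared where neither gave a call. TCP1 at 48 h lost its call without the arrays numbered 3 (1.22). Without low genes the abscisic acid, heat shock and mitochondrial stress lists had 3, 1 and 3 members and were not tested. Centring cannot move the correlation, and a block leaves the fold changes of a balanced design as they are. Low signals limit the smallest differences, and no measure of signal over background was used here.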

Other observations

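Families that share a symbol stem were examined after the data were seen, as 54 families of 5 or more genes with camera. At 6 h the IQD family of calmodulin-binding proteins had 7 of 17 genes higher than control and 3 lower (median 0.34; adjusted p = 0.0325, and adjusted p = 0.641 with an estimated correlation). The call was lost after renewed quantile normalization (0.0648). IQD22 rose by 2.76 and IQD31 by 2.01, and at 48 h against 6 h 7 of 17 were lower (adjusted p = 0.0113, and adjusted p = 0.449 with an estimated correlation). Of 5 beta-tubulin genes (TUB), 4 were lower at 48 h than at 6 h (median -1.28; adjusted p = 0.00228, and adjusted p = 0.618 with an estimated correlation), and TUB5 had risen by 2.35 at 6 h. Of 7 WRKY transcription factors 5 were higher at 6 h (median 0.92; adjusted p = 0.00378, and adjusted p = 0.641 with an estimated correlation), among them WRKY47 (1.40) and WRKY41 (0.92). This stem overlaps the early immune list, which also holds WRKY29. Genes with a CYP symbol, mostly cytochromes P450 of the CYP71B group, were lower at 6 h in 11 of 28 cases and higher in 1 (median -0.54; adjusted p = 0.00378, and adjusted p = 0.27 with an estimated correlation). CYP71B20 fell by 2.83, and 10 of the 28 were higher at 48 h than at 6 h (adjusted p = 0.00333, and adjusted p = 0.303 with an estimated correlation). The PRA genes were lower at 6 h in 7 of 16 cases (adjusted p = 0.0325, and adjusted p = 0.696 with an estimated correlation) and higher at 48 h than at 6 h in 5 (adjusted p = 0.0454, and adjusted p = 0.618 with an estimated correlation). The ATG stem, which overlaps the autophagy list, was higher at 48 h than at 6 h in 5 of 8 cases (adjusted p = 0.000912, and adjusted p = 0.449 with an estimated correlation). The medians kept their sign after centring and quantile normalization in all of these families. At 48 h against control no family was called by camera at either correlation.

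Within the chloroplast-encoded genes, classes by product were set side by side without a test of their difference. All 4 RNA polymerase genes (rpo) rose at 6 h (median 1.26), as did 8 of 13 ribosomal protein genes (median 0.66), 2 of 10 ndh genes (median 0.27), 1 of 13 psb genes (median 0.09) and 0 of 5 psa genes (median 0.06). At 48 h against 6 h the medians were -1.64, -0.93, -0.70, -0.13 and -0.15, with 4, 9, 7, 4 and 0 genes lower.

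Lists with 1 to 3 measured genes had no set test. At 6 h against control both light-harvesting genes, LHCB4.1 (-1.27) and LHCB4.2 (-1.55), fell, as did NOL of chlorophyll breakdown (-1.43) and EIN3 of ethylene signalling (-0.78). The cell wall genes EXPA8 (2.03) and EXPA4 (1.43), the starch enzyme DPE1 (1.67), the tryptophan and indole glucosinolate genes IGPS (1.15) and UGT74B1 (0.61) and the anthocyanin gene DFR (0.67) rose. At 48 h LHCB4.2 (adjusted p = 0.0185), NOL (-0.74), EXPA8 (-1.24) and the cytokinin response gene RR16 (-1.08) were lower than control, while EXPA4 (0.75), UGT74B1 (0.76), the starch enzyme AMY1 (1.19) and the clock gene GI (1.06) were higher. Of the senescence list, SAG29 fell at 6 h (-0.63), and SAG101 and WRKY6 did not pass the test at either time. The guard cell marker FMA was higher at 6 h (adjusted p = 0.00014) and 48 h (0.62) and GASA9 lower (-0.93 and -0.97), and the phloem marker SWEET11 had 0.10 and 0.07 (adjusted p = 0.736 and 0.854). Jasmonate genes PDF1.2 and THI2.1, STZ of reactive oxygen defence and BGLU28 of sulfur deficiency did not pass the test in any comparison. Lists of dark- and starvation-induced, salicylic acid, aliphatic glucosinolate, nitrate assimilation, cell cycle, epidermis, xylem, flower and seed and mitochondria-encoded genes had no measured member and were not analysed here. Their members may lie among the entries that were not listed or that had several genes.

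Tested lists without a camera call were endoplasmic reticulum folding (adjusted p = 0.873 at 6 h, 0.65 at 48 h, 0.989 at 48 h against 6 h) and mitochondrial stress (0.725, 0.135 and 0.0896). In the first, DER1 fell at 6 h (-1.47), and in the second UPOX rose at 48 h (1.36). Over all genes 1, 0 and 1 folding genes were higher and 1, 1 and 1 lower, with 2, 0, 1 and 1, 1, 1 adjusted over the list alone. For mitochondrial stress 0, 1 and 2 were higher and 1, 0 and 0 lower, with 1, 1, 3 and 2, 0, 0 adjusted over the list alone. Photosystem subunits were lower in 2 of 4 cases at 6 h (list adjusted p = 0.097) and in 3 at 48 h against 6 h (0.0734). Xenobiotic detoxification genes were lower in 2 of 9 cases at 6 h (0.104). At 48 h against control chlorophyll synthesis (0.93), autophagy (0.821), abscisic acid (0.569) and auxin response (0.93) were not called, and at 48 h against 6 h neither were early immune (0.989), auxin (0.989), heat shock (0.478) or hypoxia genes (0.478). The sign of the median differed from that of the test for folding at 6 h and 48 h against 6 h, for chlorophyll synthesis, autophagy and auxin at 48 h, and for early immune genes at 48 h against 6 h. For auxin at 48 h against 6 h both the median and the mean were below 0 while the test pointed up.

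The 6 arrays of each comparison can be split in 10 ways, too few for a share under 0.05. Every other split mixes the groups, so that a difference between them adds to the spread and removes calls. The counts of the other splits are therefore no measure of chance. For 6 h against control 1 split, the real one, gave as many genes (4531 against at most 0 in the others by limma, with 747 at an unadjusted p under 0.05 against 6212) and as many lists (5 against at most 4). For 48 h against control the real split gave 1762 genes against at most 0 (3951 against 1896 unadjusted) and 6 lists against at most 2. There the 3 other splits that part all 3 pairs of numbers gave at most 342 genes unadjusted, and the 6 that part 1 pair gave up to 1896. For 48 h against 6 h it gave 3356 genes against at most 0 (5059 against 460 unadjusted) and 5 lists against at most 4.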
